A study of Mus musculus with 80 samples.

How the data were processed

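Gene expression was measured in mammary tumours of mice that carried Myc under the mouse mammary tumour virus promoter, a transgene that drives the Myc oncogene in mammary epithelium. Per the labels, the mice were of the FVB strain, each tumour was frozen, and total RNA was taken with a Qiagen RNeasy Midi kit, labelled with biotin and hybridised to a 1-colour Affymetrix array. The series holds 80 arrays, 1 per tumour, with 20 from each of 4 backgrounds: wild type for the E2F genes, null for E2F1, null for E2F2, or heterozygous for E2F3. The deposited values are intensity values on a linear scale, made by the authors with the MAS5 algorithm in Affymetrix Expression Console; the versions are not given in the sources used here.

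The deposited table holds 22690 probe sets with 0 missing values, from 0.0275 to 29812. On each array, the mean without the highest and lowest 2% of values lay between 500.17 and 500.22, so the authors had scaled the arrays to a common mean of about 500. A change in the total amount of mRNA per cell therefore cannot be seen in these values. After 64 Affymetrix control probe sets were left out, 22626 remained. Of these, 20380 carried 1 gene symbol in the probe table, 691 carried several and 1555 carried none; the last 2 kinds were not used for named genes. Chromosomes, and distances between gene starts, came from the RefSeq table of the mouse assembly GRCm38.p6. The deposited files name no genome build, so no coordinates are printed.

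Intensities were converted to log2(value + 5), where 5 is the rounded 10th percentile of all values. A probe set was kept if it exceeded 74.6, the 40th percentile, on at least 10 of the 80 arrays. For genes with several probe sets, the one with the highest mean was used. These steps left 8766 tested genes of 12393 genes on the array.

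Samples were grouped by genotype. Each label also holds a number before a hyphen, and 46 arrays shared this number with another array of the same genotype. What the number stands for is not given in the sources used here. Because tumours sharing it may come from 1 animal, the number was used as a random block, with 16 numbers in wild type, 16 in E2F1 null, 11 in E2F2 null and 10 in E2F3 heterozygous tumours. The block was fitted with limma 3.58.1 and statmod 1.5.0 in R 4.3.3, and its consensus correlation was 0.159. Each mutant background was compared with wild type, the backgrounds were compared with each other, and a moderated F test covered all 4 genotypes. Moderation used an intensity trend and the robust option, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Arrays give no read counts, and their number limits the precision: the median SE of a log2 fold change was 0.117, 0.12 and 0.12 in E2F1 null, E2F2 null and E2F3 heterozygous tumours against wild type.

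For 29 gene lists, the score of a tumour was the mean over tested members of the log2 value minus the mean of that gene over all 80 arrays. Scores were averaged per label number and compared by a permutation test with 100000 resamples, two-sided, adjusted over all lists and the 3 comparisons; intervals are Welch intervals at 95%. The lists were E2F and pocket protein family, DNA replication and G1/S, mitosis and G2/M, p53 and apoptosis, DNA damage and repair, Myc targets and ribosome biogenesis, luminal epithelium, milk and secretory differentiation, basal and myoepithelial, keratinization and squamous, epithelial to mesenchymal transition, fibroblast and collagen matrix, adipocyte, T and NK cell, B cell and plasma cell, macrophage and myeloid, neutrophil, MHC class II, interferon response, endothelial, hypoxia and glycolysis, skeletal muscle, Wnt pathway output, RAS and MAPK output, immediate early and heat shock, cholesterol and fatty acid synthesis, oxidative phosphorylation, unfolded protein response, and circadian clock. The set tests camera, with a preset and with an estimated correlation between genes, and fry were run beside the permutation test. Camera compares a list with other genes, and fry tests whether the members of a list move, on balance, one way. Fold changes of list members, and counts of members higher or lower, came from the limma fit over arrays. In that fit a label number with several tumours weighs more than in the list score.

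One-sided Fisher exact tests asked whether called genes lay on the chromosome of the targeted gene more often than other tested genes. The spread between tumours was the root mean square distance, over the 1000 most variable genes, to the mean profile of the genotype computed without that label number. Array quality was followed by the median log2 value and by the ratios of the 3' to the 5' control probe sets of Gapdh and beta-actin. These calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

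The comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except where a later choice is stated. By that rule, E2f1, E2f2, E2f3 and Myc were always named, together with up to 12 genes with the highest and 12 with the lowest fold change past the threshold. Where fewer than 5 genes passed, the 5 with the smallest p were named too, and for a described list the 2 members with the smallest p. Up to 5 genes in each direction were named for comparisons between mutant backgrounds, 10 for the F test, and called genes within 20 Mb of a targeted gene. Alternatives covered the block, normalization, pseudocount, filter, choice of probe set, array weights, covariates, moderation and a 2-fold minimum. Leaving out E2F1 null replicate 6, and adding the skeletal muscle score or the medians of chromosomes 6 and 15 as covariates, were chosen after the data were seen. The models were tested on simulated data with known changes in 200 genes per comparison. E2f2 has no probe set under its name in the probe table, so it was not analysed here.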

Results

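The series asks how the loss of single E2F transcription factors, which act downstream of the retinoblastoma protein in cell cycle entry, alters tumours driven by Myc. It holds 80 mammary tumours, 20 from each of 4 genotypes, and 1 array per tumour. The median correlation between 2 arrays over all probe sets was 0.949, and the range was 0.867 to 0.979. E2F1 null replicate 6 stood apart from the other arrays: over the tested genes its mean correlation with the others was 0.807, the next lowest was 0.847 and the median was 0.906. This tumour had the highest fibroblast and collagen matrix score, 3.52, and the lowest luminal epithelium score, -1.01. Array quality did not differ detectably between genotypes. The smallest unadjusted p, 0.183 by a permutation test over label numbers, was for the Gapdh 3' to 5' ratio in E2F2 null tumours, with a log2 ratio of -0.31 ± 0.06 (SD, n = 11) against -0.28 ± 0.07 (SD, n = 16) in wild type.

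The targeted genes and the transgene were examined first. Myc gave a log2 signal of 13.48 ± 0.22 (SD, n = 20) in wild type, 13.49 ± 0.29 in E2F1 null, 13.55 ± 0.27 in E2F2 null and 13.46 ± 0.26 in E2F3 heterozygous tumours. Its smallest unadjusted p against wild type was 0.425, for a log2 fold change of 0.07 (SE 0.09) in E2F2 null tumours. The array measured E2f1 with 2 probe sets. By 1 of them, the signal was 6.38 ± 0.45 (SD, n = 20) in E2F1 null tumours against 6.98 ± 0.44 in wild type, a log2 fold change of -0.59 (SE 0.14, p = 4.2e-05, adjusted p = 0.0625 over all probe sets of single genes and 0.0469 over the 14092 that passed the filter). By the other, which is the brighter and was used for the gene-level test, the signal was 6.95 ± 0.42 against 7.13 ± 0.26, with a log2 fold change of -0.19 (SE 0.10, p = 0.0793). E2f3, a heterozygous allele in 20 tumours, gave 6.51 ± 0.43 in these against 6.72 ± 0.26 in wild type, a log2 fold change of -0.19 (SE 0.12, p = 0.115). Which exons the engineered alleles lack, relative to these probe sets, is not given in the sources used here, and E2f2 was not analysed here for want of a named probe set.

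Tumours without E2F1 differed from wild type in 4 genes past the threshold, all on chromosome 2, the chromosome that carries E2f1. Rbbp9, which encodes a retinoblastoma-binding serine hydrolase, rose 3.76-fold, from a log2 signal of 6.37 ± 0.40 (SD, n = 20) to 8.27 ± 0.42 (SD, n = 20). Its log2 fold change was 1.91 (SE 0.13, limma adjusted p = 3.58e-21), and all 20 E2F1 null tumours lay above every wild-type tumour. Mapre1, which encodes the microtubule plus-end protein EB1, fell 1.9-fold by its brightest probe set, with a log2 fold change of -0.92 (SE 0.07, adjusted p = 9.54e-18) and 18 of 20 tumours below every wild-type tumour. Cdk5rap1, a mitochondrial tRNA-modifying enzyme, rose by a log2 fold change of 0.51 (SE 0.10, adjusted p = 0.00268), with 9 of 20 tumours above every wild-type tumour. Pofut1, an O-fucosyltransferase that modifies Notch receptors, had a log2 fold change of -0.53 (SE 0.11, adjusted p = 0.0173), with 13 of 20 tumours below every wild-type tumour. Bpifb5 had the next smallest p, with a log2 fold change of 0.97 (SE 0.22, adjusted p = 0.0687). The wild-type mean of Rbbp9 lay close to the log2 filter threshold of 6.31, and the means of Pofut1 (5.65 ± 0.34 against 6.18 ± 0.25 in wild type) and Bpifb5 (6.25 ± 0.98 against 5.26 ± 0.46) lay below it, so the sizes of these changes are uncertain.

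Measured from gene start to gene start, Rbbp9 lay 10 Mb from E2f1, Pofut1 1.3 Mb, Mapre1 0.8 Mb, and Cdk5rap1 and Bpifb5 0.3 Mb. Chromosome 2 held 7.9% of the tested genes and 4 of the 4 called genes (Fisher exact p = 3.87e-05, one-sided). At an unadjusted p under 0.001 it held 10 of 11 genes (Fisher exact p = 9.14e-11). The other genes of chromosome 2 at that level were Snhg11, Rin2 and Zcchc3 with higher signals, and Norad and Nfs1 with lower ones, and the gene outside it was Pnpt1 on chromosome 11; these were chosen after their values were seen. Within 20 Mb of E2f1, 13.2% of 197 genes had an unadjusted p under 0.05, against 1.62% of 495 genes on the rest of chromosome 2 and 0.97% of 8065 genes on other chromosomes. Over all 8766 genes the count at that level was 113, against 438 by chance. Other detected probe sets of Mapre1 disagreed in size, with log2 fold changes of -0.24, -1.28 and 0.04, and Zcchc3 had 0.31 by the tested probe set and -1.33 by another; Rbbp9 and Cdk5rap1 had no other detected probe set. With every probe set tested on its own, 13 probe sets of 12 genes passed; 12 of the 13 lay within 20 Mb of E2f1, among them 1 of E2f1 itself and 2 of Mapre1. Without E2F1 null replicate 6, an alternative chosen after the data were seen, 6 genes passed, Bpifb5 among them (adjusted p = 0.0102; its range over all alternatives was 0.000842 to 0.346).

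**Figure D1:**
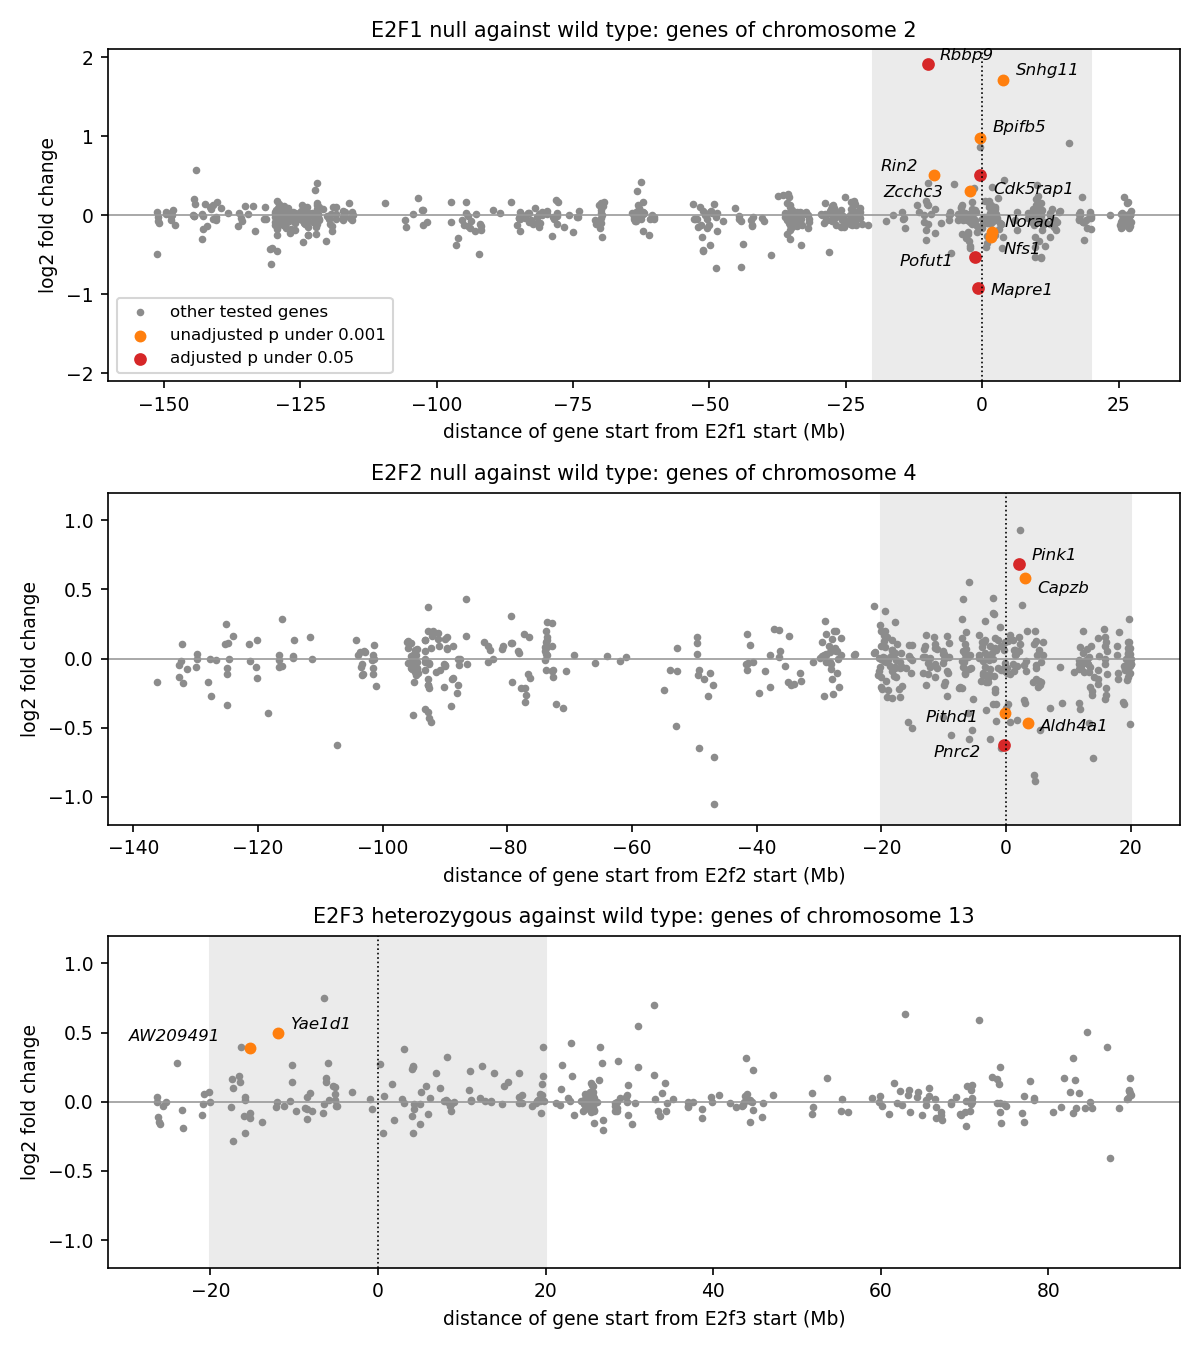
Log2 fold change against wild type of each tested gene on the chromosome of the targeted gene (vertical axis), by the distance of its start from the start of E2f1, E2f2 or E2f3 in megabases (horizontal axis), with the targeted gene itself left out. Red points passed an adjusted p of 0.05, orange points an unadjusted p of 0.001, grey bands span 20 Mb on each side, and all coloured points lie in these bands.

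**Figure D2:**
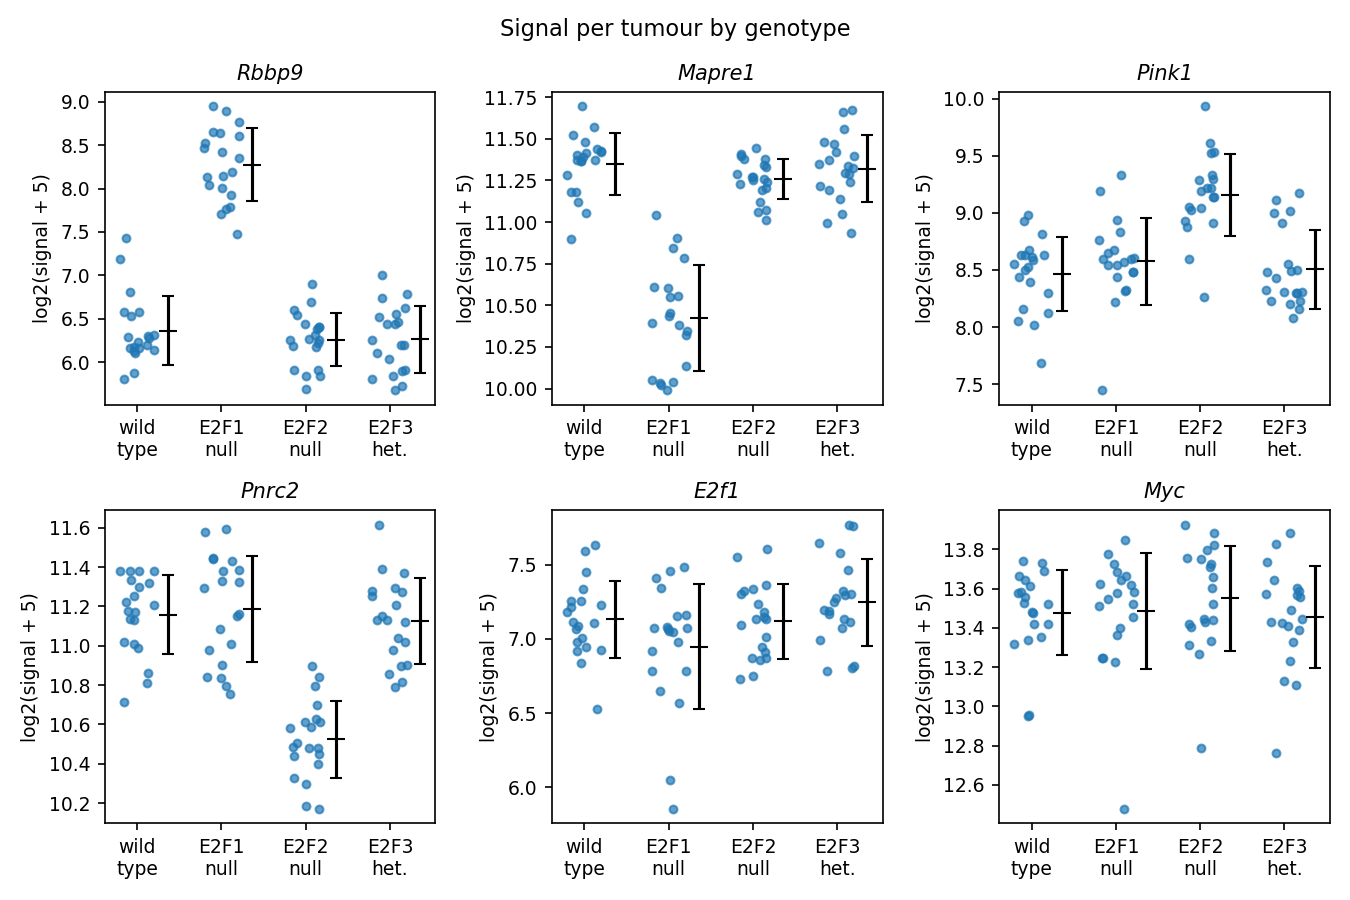
Log2 signal of 6 genes in each tumour (points, n = 20 per genotype), with the mean and SD beside each group; each panel has its own vertical range. Rbbp9 in E2F1 null tumours reached from 7.47 upward, above the highest value of the other 60 tumours, 7.43, while the Myc groups overlapped.

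None of the 29 gene lists shifted in E2F1 null tumours: the permutation test gave an adjusted p of 0.998 for each, and 0 lists had an unadjusted p under 0.05. No member of any list changed, over all genes tested or adjusted over the list alone, for which 0 members rose and 0 fell. The E2F and pocket protein family had 10 measured members, among them the targeted E2f1 (log2 fold change -0.19), which thus enters the score. The score difference of this list was -0.05 (SE 0.05, 95% interval -0.14 to 0.05). Its member E2f8 had a log2 fold change of -0.24 (SE 0.12, limma p = 0.0475). DNA replication and G1/S genes had a difference of 0.08 (SE 0.11, 95% interval -0.14 to 0.30), and mitosis and G2/M genes 0.07 (SE 0.14, 95% interval -0.21 to 0.35). E2F1 null replicate 6, which stood apart, scored -0.45 for the E2F family, -0.75 for replication, -0.89 for mitosis and -1.01 for luminal genes. List differences without it were not analysed here. Hypoxia and glycolysis genes came closest to the threshold, with a difference of -0.19 (SE 0.10, p = 0.0694) and lower values in 19 of 20 members, such as Bnip3 at -0.47 (SE 0.29) and Pfkfb3 at -0.30 (SE 0.19). RAS and MAPK output genes, which include feedback regulators of this pathway, were higher in 12 of 12 members, with a difference of 0.32 (SE 0.34, p = 0.348), Spred2 at 0.31 (SE 0.19) and Epha2 at 0.33 (SE 0.26). Differences were -0.10 for luminal epithelium, -0.27 for basal and myoepithelial, -0.16 for keratinization and squamous, -0.10 for cholesterol and fatty acid synthesis, -0.09 for unfolded protein response, -0.03 for circadian clock and 0.00 for oxidative phosphorylation genes. Camera with its preset correlation called 5 lists (hypoxia, RAS and MAPK, luminal, basal and cholesterol), and none of these calls held with an estimated correlation (adjusted p = 0.904 for each) or by fry (adjusted p = 0.983).

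Tumours without E2F2 differed from wild type in 2 genes, both on chromosome 4 near E2f2. Pnrc2, which encodes a nuclear receptor coactivator also linked to mRNA decay, fell 1.54-fold, from 11.16 ± 0.20 (SD, n = 20) to 10.52 ± 0.20 (SD, n = 20). Its log2 fold change was -0.62 (SE 0.08, limma adjusted p = 2.66e-08), with 17 of 20 tumours below every wild-type tumour, and its start lay 0.3 Mb from that of E2f2. Pink1, a kinase that marks damaged mitochondria for removal, rose 1.61-fold, from 8.46 ± 0.33 to 9.16 ± 0.36. Its log2 fold change was 0.69 (SE 0.12, adjusted p = 0.000726), with 15 of 20 tumours above every wild-type tumour, and it lay 2.1 Mb from E2f2. The next smallest p-values belonged to Csgalnact2 at -0.49 (SE 0.12, adjusted p = 0.207), the actin-capping gene Capzb at 0.58 (SE 0.15, adjusted p = 0.521) and Emc3 at -0.30 (SE 0.08, adjusted p = 0.521). Capzb is on chromosome 4, 3.0 Mb from E2f2; Csgalnact2 and Emc3 are on chromosome 6, whose genes were shifted upward together in 27 of the 80 tumours, 10 of them wild type and 3 E2F2 null.

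Chromosome 4 held 6.26% of the tested genes and both called genes (Fisher exact p = 0.00391, one-sided). It held 5 of 11 genes at an unadjusted p under 0.001 (Fisher exact p = 0.000317), and 4 of the 11 were on chromosome 6. Within 20 Mb of E2f2, 10.96% of 292 genes had an unadjusted p under 0.05, against 5.08% of 256 genes on the rest of chromosome 4 and 6.0% of 8210 genes elsewhere. Over all 8766 genes the count at that level was 538, against 438 by chance. A further probe set of Pnrc2 had a log2 fold change of -0.27, those of Capzb had 0.41 and 0.48, and Pink1 had no other detected probe set. With every probe set tested on its own the count was 5, all within 20 Mb of E2f2: Pnrc2, Pink1, Cdc42, Mul1 and Eloa, the last 3 named after their values were seen.

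None of the 29 gene lists shifted in E2F2 null tumours (adjusted p = 0.998 for each), and 1 list had an unadjusted p under 0.05. In each list, 0 members rose and 0 fell, over all genes tested and adjusted over the list alone. Mitosis and G2/M genes were higher in 32 of 34 members, with a difference of 0.26 (SE 0.12, 95% interval 0.02 to 0.50, p = 0.0566), Plk1 at 0.36 (SE 0.12) and Kif20a at 0.34 (SE 0.16). DNA replication and G1/S genes were higher in 29 of 35 members, with a difference of 0.21 (SE 0.10, 95% interval -0.001 to 0.41, p = 0.0647), Cdt1 at 0.26 (SE 0.11) and Chaf1b at 0.24 (SE 0.11). DNA damage and repair genes were higher in 14 of 14 members, with a difference of 0.20 (SE 0.09, p = 0.0483), Brca2 at 0.24 (SE 0.11) and Fanci at 0.31 (SE 0.14). The p53 and apoptosis genes were lower in 19 of 20 members, with a difference of -0.33 (SE 0.14, p = 0.0533), Gadd45a at -0.78 (SE 0.31) and Cdkn2a at -0.71 (SE 0.35). Interferon response genes were higher in 28 of 28 members, with Psmb8 at 1.03 (SE 0.32) and Bst2 at 0.80 (SE 0.31). The score difference was 0.25 (SE 0.34, 95% interval -0.45 to 0.96, permutation p = 0.449). The score weighs each label number equally, while in the member values label numbers with several tumours weigh more. Label number 4010, with 4 E2F2 null tumours, had interferon scores from 0.33 to 1.95. Differences were 0.09 for the E2F and pocket protein family, 0.12 for Myc targets and ribosome biogenesis, 0.30 for milk and secretory differentiation, 0.01 for adipocyte, -0.39 for epithelial to mesenchymal transition, -0.44 for neutrophil and -0.25 for endothelial genes. Camera with its preset correlation called 12 lists, and none of these calls held with an estimated correlation (adjusted p = 0.904 for each of the 12) or by fry (adjusted p = 0.983).

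Tumours heterozygous for E2F3 differed from wild type in 0 genes by limma, with 58 genes at an unadjusted p under 0.05, against 438 by chance, and 3 at an unadjusted p under 0.001. Of these 3, AW209491 and Yae1d1 are on chromosome 13, which carries E2f3 and held 3.54% of the tested genes (Fisher exact p = 0.00366, one-sided, at this level; with 0 called genes the test on called genes is void). AW209491 had a log2 fold change of 0.39 (SE 0.10, p = 0.000142, adjusted p = 1), with 11 of 20 tumours above every wild-type tumour. Yae1d1 had 0.50 (SE 0.14, p = 0.000437) by the tested probe set and -0.50 by another, which was the 1 probe set that passed when every probe set was tested on its own (adjusted p = 0.00198). Ccne2, which encodes cyclin E2, had a log2 fold change of -0.57 (SE 0.15, p = 0.000413, adjusted p = 1), from 8.26 ± 0.42 (SD, n = 20) to 7.65 ± 0.41, with 7 of 20 tumours below every wild-type tumour. Mmaa had -0.26 (SE 0.09, p = 0.00492) and Sel1l3 had 0.62 (SE 0.22, p = 0.00609), with means of 6.30 and 5.71, below the log2 filter threshold of 6.31.

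None of the 29 gene lists shifted in E2F3 heterozygous tumours (adjusted p = 0.998 for each), and 0 had an unadjusted p under 0.05. Of the DNA replication and G1/S genes, 1 of 35, Ccne2, fell adjusted over the list alone, and 0 did over all genes tested; the list had a difference of 0.07 (SE 0.10, 95% interval -0.14 to 0.28). In the other lists 0 members rose and 0 fell by either adjustment. Skeletal muscle genes had the largest difference, 0.77 (SE 0.53, 95% interval -0.32 to 1.87, p = 0.183), with higher values in 18 of 18 members, Eno3 at 0.32 (SE 0.19) and Tnnt3 at 1.01 (SE 0.67). Fibroblast and collagen matrix genes were higher in 20 of 22 members, with a difference of 0.25 (SE 0.41, p = 0.588), Mfap5 at 0.49 (SE 0.35) and Col3a1 at 0.40 (SE 0.30). Differences were 0.34 for neutrophil, 0.34 for B cell and plasma cell (3 members), -0.05 for T and NK cell (2 members), -0.07 for MHC class II (4 members), -0.001 for macrophage and myeloid, 0.16 for Wnt pathway output and 0.08 for immediate early and heat shock genes. Camera with its preset correlation called 10 lists, and none held with an estimated correlation (adjusted p from 0.904 to 0.990) or by fry (adjusted p = 0.983). The mean, the median and the set tests differed in sign for 5 lists in E2F1 null, 5 in E2F2 null and 7 in E2F3 heterozygous tumours, all with score differences between -0.09 and 0.07.

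**Figure D3:**
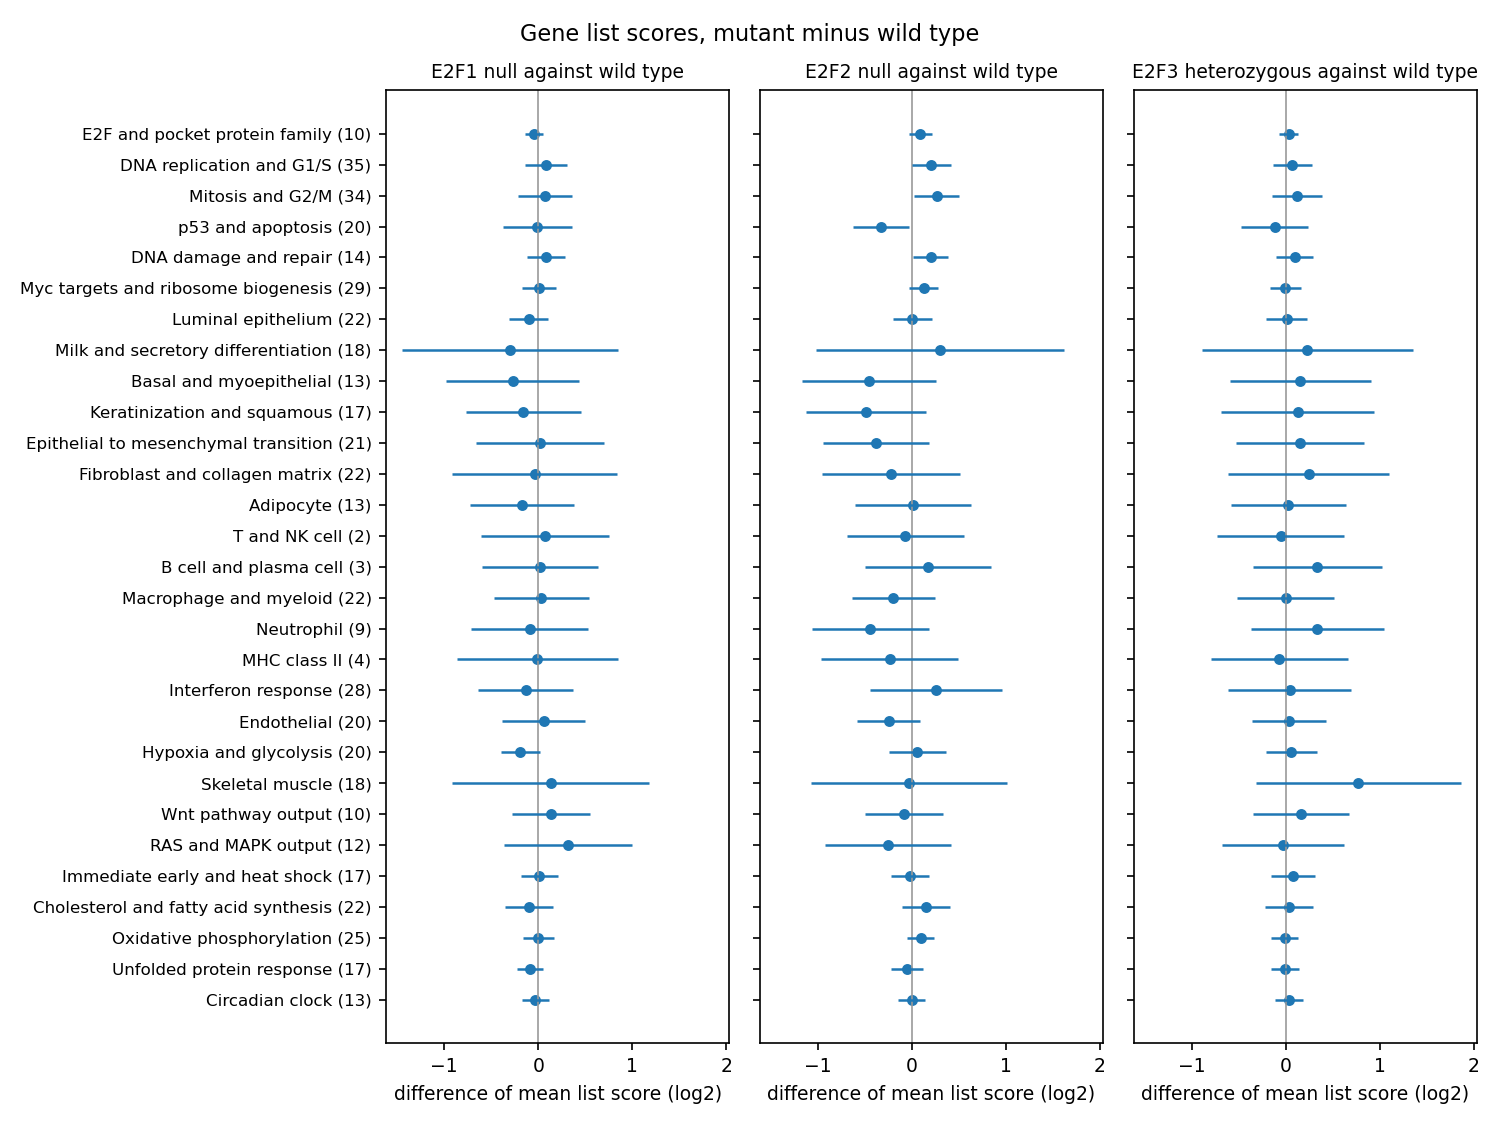
Difference of the mean list score between each mutant background and wild type in log2 units (points) with its 95% Welch interval (lines) over label numbers (16 in wild type and in E2F1 null, 11 in E2F2 null, 10 in E2F3 heterozygous), for 29 lists with the number of measured members in brackets. The permutation test gave an adjusted p of 0.998 for each difference.

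Most genes that differed between mutant backgrounds also lay on a chromosome that carries a targeted gene. E2F1 null and E2F2 null tumours differed in 14 genes, 10 higher and 4 lower in E2F1 null, of which 8 were on chromosome 2, 5 on chromosome 4 and 1, Erdr1, on the X chromosome. Log2 fold changes, E2F1 null over E2F2 null, were 2.00 (SE 0.13) for Rbbp9, 0.91 (SE 0.21) for Erdr1, 0.67 (SE 0.13) for Rin2, 0.67 (SE 0.13) for Pdrg1 and 0.65 (SE 0.08) for Pnrc2. On the lower side they were -0.83 (SE 0.07) for Mapre1, -0.70 (SE 0.15) for Capzb, -0.59 (SE 0.12) for Pink1 and -0.51 (SE 0.12) for Pofut1. E2F1 null and E2F3 heterozygous tumours differed in 7 genes: Rbbp9 (2.00), Pdrg1 (0.64), Cdk5rap1 (0.54), Zcchc3 (0.43) and Mapre1 (-0.89) on chromosome 2, Pnpt1 (0.56) on chromosome 11 and AW209491 (-0.43) on chromosome 13. E2F2 null and E2F3 heterozygous tumours differed in 3 genes, Pink1 (0.65), Pnrc2 (-0.60) and AW209491 (-0.47). By the moderated F test, 13 genes differed among the 4 genotypes, 7 on chromosome 2, 4 on chromosome 4, and AW209491 and Pnpt1. The smallest adjusted p-values were 2.07e-25 for Rbbp9, 9.77e-20 for Mapre1, 1.8e-10 for Pnrc2, 0.000379 for Pink1, 0.000444 for Cdk5rap1 and 0.00283 for Pdrg1, followed by Rin2, Pofut1, Zcchc3 and AW209491 with values from 0.00756 to 0.0184. With 1 mean per label number and no block, the counts between backgrounds dropped to 7, 3 and 1, and that of the F test to 8. A further probe set of Pnpt1 changed in the opposite direction in E2F1 null tumours, with a log2 fold change of -1.05 (SE 0.18, adjusted p = 0.000176 among all probe sets).

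The loss of an E2F gene did not detectably alter how far tumours of a genotype spread around their mean. The distance was 1.41 ± 0.20 (SD, n = 16 label numbers) in wild type, 1.40 ± 0.30 (n = 16, p = 0.863) in E2F1 null, 1.32 ± 0.16 (n = 11, p = 0.18) in E2F2 null and 1.32 ± 0.19 (n = 10, p = 0.248) in E2F3 heterozygous tumours, by two-sided permutation tests against wild type. Tumours sharing a label number were only slightly more alike than others of their genotype. The mean correlation of genotype-centred profiles was 0.036 over 36 pairs that shared a number and -0.054 over 724 pairs that did not, a difference of 0.089 (p = 0.054, one-sided permutation test). Over all tested genes instead of the 1000 most variable, the difference was 0.115 (p = 0.0109).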

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

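Leaving out E2F1 null replicate 6 and adding the skeletal muscle score or the chromosome 6 and 15 medians as covariates were chosen after the data were seen; these left 6, 4 and 4 genes in E2F1 null, 2 in E2F2 null and 0 in E2F3 heterozygous tumours. No paired analysis was possible because no label number occurs in more than 1 genotype and replicate numbers only follow the order of the arrays. Of 110 values of the main results under alternatives, 92 kept their direction and side of the threshold or stayed within 1.5 times the count, 16 counts moved by more, 2 passed a threshold that they had missed, and 0 reversed. In E2F1 null tumours the count of 4 became 2 under the stricter filter, which left Cdk5rap1 and Pofut1 untested, 9 with array weights, 13 with every probe set and 1 with a 2-fold minimum. In E2F2 null tumours the count of 2 became 5 with every probe set and 0 with a 2-fold minimum (538 genes at an unadjusted p under 0.05 by limma), and in E2F3 heterozygous tumours 0 became 1 with every probe set. With the mean per label number, which leaves fewer samples, the genes differing between E2F1 null and E2F2 null went from 14 to 7, between E2F1 null and E2F3 heterozygous from 7 to 3, between E2F2 null and E2F3 heterozygous from 3 to 1, and among the 4 genotypes from 13 to 8. The last count was also 8 after quantile normalization, and that between E2F2 null and E2F3 heterozygous was 5 with no block; except where stated, the cause was not tested. Camera with preset correlation called 5, 12 and 10 lists in E2F1 null, E2F2 null and E2F3 heterozygous tumours, where the permutation test, camera with an estimated correlation and fry called 0. Similarity within label numbers became 0.115 over all tested genes, and 2 genes of chromosome 13 passed an unadjusted p under 0.001 in E2F3 heterozygous tumours. Of 401 values for named genes, which leave out the 2-fold minimum and the test of every probe set, 386 kept their call, 12 lost it, all in comparisons between mutant backgrounds, and 3 gained it, all for Bpifb5. How recovery depends on signal over background was not analysed here. Data were simulated with the measured spread of each gene. Noise was drawn independently for each gene, unlike the real arrays, where genes of chromosomes 6 and 15 moved together. In these data, 8, 11 and 11 of 50 genes with a log2 change of 0.25 were recovered in E2F1 null, E2F2 null and E2F3 heterozygous tumours. At a change of 0.5 it was 28 in each, at 1 it was 46, 42 and 44, and at 2 it was 50, 49 and 49. False calls were 19, 8 and 9. Their share of all calls exceeded the threshold of 0.05 in each comparison, most in E2F1 null tumours. These simulations changed 200 genes per comparison, far more than were called in the real data against wild type. With few changed genes the adjustment would be stricter, so the recovered numbers overstate what would be found then. In simulations of list scores, all 29 lists were shifted at once in E2F2 null tumours and drawn independently of each other. With few shifted lists the adjustment would be stricter, so the counts overstate what would be found then. The shift was called in 15 of 29 lists at a size of 0.5, 23 at 1 and 29 at 2. In the other comparisons, where no shift was simulated, 0 lists were called in the first of these simulations, 2 in each comparison in the second, and 0 in E2F1 null and 1 in E2F3 heterozygous tumours in the third.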

Other observations

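The relations between lists, the medians per chromosome, the comparison of probe sets, the reading of the fibroblast tests, the chromosome 6 comparison of genotypes and both tests of the remaining E2f1 signal were chosen after the result was seen; the Fisher tests of called genes were chosen before, and their use against genome-wide regulation after.

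Most of the variation between tumours in list scores lay within genotypes. The milk and secretory differentiation score (caseins, Wap and other milk genes) ranged from -3.22 to 3.23 over 80 tumours (SD 1.56, and 1.54 with genotype means removed), the skeletal muscle score from -2.04 to 3.07 (SD 1.44) and the interferon response score from -1.32 to 3.68 (SD 0.96), while the E2F and pocket protein family had an SD of 0.16. Over 53 label numbers and 325 pairs of lists with at least 5 genes, 154 pairs were correlated at an adjusted p under 0.05. Milk genes ran against RAS and MAPK output genes, with r = -0.72 and rho = -0.71 (both permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 5e-05), r = -0.71 without the 2 farthest label numbers, and r = -0.86 within wild type, -0.64 within E2F1 null, -0.65 within E2F2 null and -0.69 within E2F3 heterozygous tumours (16, 16, 11 and 10 label numbers). Oxidative phosphorylation genes ran against Wnt pathway output genes, with r = -0.83 and rho = -0.90 (both permutation p = 1e-05, adjusted p = 5e-05), r = -0.86 without the 2 farthest, and -0.90, -0.84, -0.89 and -0.70 within the genotypes in the same order. Myc targets and ribosome biogenesis genes ran against endothelial genes, with r = -0.73 (permutation p = 1e-05, adjusted p = 5e-05), rho = -0.60 (permutation p = 2e-05) and r = -0.62 without the 2 farthest. Within genotypes that relation had r = -0.78, -0.80, 0.21 and -0.80, so it was not seen in E2F2 null tumours. Whether the genotypes differ in it was not tested. E2F1 null replicate 6, with the highest fibroblast score, also had the highest endothelial score (1.81) and the lowest Myc target score (-0.84). Whether the mix of cells in a tumour sets these relations between lists was not tested.

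Genes of whole chromosomes also moved together in single tumours. The chromosome 6 median, relative to all genes of the tumour, lay above 0.15 in 27 of 80 tumours, below -0.05 in 48 and between in 5, and that of chromosome 15, which carries Myc, above 0.15 in 29, below -0.05 in 41 and between in 10. Above 0.15 for chromosome 6 were 10 wild-type, 9 E2F1 null, 3 E2F2 null and 5 E2F3 heterozygous tumours of 20 each, and for chromosome 15 there were 8, 5, 8 and 8. Of 19 label numbers with several tumours, 11 had tumours on both sides of 0 for chromosome 6 and 12 for chromosome 15. Other chromosomes moved in few tumours: chromosome 8 exceeded 0.15 in 5 and chromosome 11 in 6, single tumours reached 0.40 on chromosome 1 and 0.44 on chromosome 18, and the lowest value was -0.42 on chromosome 14. All 22 genes of the fibroblast and collagen matrix list were measured in these tumours, with mean log2 signals of 12.09 for Col3a1 and 10.99 for Col1a1. For chromosome 6, 19 genes of this list were used, those on that chromosome left out. The list shares 0 genes with the epithelial to mesenchymal transition list. Even so, E2F1 null replicate 6 and wild-type replicate 6 had the highest fibroblast scores (3.52 and 3.00) and the highest transition scores (2.55 and 1.92). The fibroblast score may therefore not measure fibroblasts alone. With 60 tests of a chromosome median against wild type, the smallest adjusted p was 0.981.

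The first pattern is that genes called in E2F null tumours lie near the targeted gene. The one-sided Fisher tests, p = 3.87e-05 for E2F1 null and 0.00391 for E2F2 null, argue against regulation by E2F proteins across the genome as the whole cause. A chromosome segment that came with the engineered allele from another strain is a candidate explanation. Each region was enriched for genes with an unadjusted p under 0.05 in its own genotype (Fisher exact p = 5.57e-20, 0.00106 and 0.00585 for E2f1, E2f2 and E2f3). In the other genotypes the smallest Fisher exact p was 0.143. For E2f3 the enrichment rests on 4 of 107 genes (3.74%), fewer than chance would give, against 0.64% on other chromosomes. These tests take neighbouring genes as independent. For E2f1 and E2f2 they rest on the same p-values as the pattern itself. A local effect of the missing gene or of the inserted sequence would give the same enrichment, so they do not favour the segment over it. A sequence difference under single probe sets may also contribute, since Zcchc3 and Yae1d1 had probe sets moving in opposite directions. Of 11 other detected probe sets, 7 (63.6%) moved the same way with a limma p under 0.05, a share that leaves this undecided. These 11 belong to genes whose tested probe set had p under 0.001. Genes called only by another probe set, such as Tgm2 (-1.71), Rbm39 (-1.21) and Crnkl1 (-0.69) in E2F1 null tumours, were left out. Norad counts as moving the same way, although its log2 fold changes were -0.21 and -1.93. Sequence differences under probe sets cannot be told apart from changes of transcript level, as only 7 of 17 genes had another detected probe set. An effect of the missing E2F gene or of the inserted sequence on its neighbours stays open and was not tested.

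The second pattern is the shift of chromosomes 6 and 15, for which a change in copy number in the tumour cells is a candidate explanation. Array scaling or noise was examined through random parts of the genes of each chromosome. Their medians correlated at r = 0.978 for chromosome 6 and 0.974 for chromosome 15, above the highest of 100 random gene sets, 0.616 and 0.666. Genes of each chromosome thus moved together more than random genes did. Both chromosomes stand out by the size of their shift, which favours such values, so this is not independent support against noise. If tumour cells carry the shift, fibroblasts would dilute it, and for chromosome 6 the fibroblast score fell with the median above 0 (r = -0.42, permutation p = 0.0235, rho = -0.39, permutation p = 0.0367, adjusted p = 0.0471, n = 29 label numbers, r = -0.70 without the 2 farthest); for chromosome 15 r was -0.17 (permutation p = 0.38, rho = -0.17, adjusted p = 0.452, n = 30), which leaves dilution undecided there. Below 0 the score rose with the median of chromosome 6 (r = 0.42, permutation p = 0.0117, rho = 0.49, adjusted p = 0.0466, n = 35). For chromosome 15 r was 0.13 there (permutation p = 0.452), in this family of 4 relations. The fibroblast score may not measure fibroblasts alone, which limits any reading of these relations as dilution. The values below 0 cannot decide on dilution of a gain. Centring sets this 0, tumours without the gain would stay in place, and a strongly diluted gain could also lie below it. That loss of E2F2 lowers the share of tumours with the chromosome 6 shift also stays open, with a mean median lower by a difference of -0.12 against wild type (permutation p = 0.0998); DNA copy number was not analysed here.

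The third pattern is the E2f1 signal that remained in E2F1 null tumours. Mislabelled samples are argued against as the cause across these tumours, since 0 of 20 labelled E2F1 null had Rbbp9 within the range of the other 60. Rbbp9 was picked because it separates the genotypes, its ranges lie close (7.47 and 7.43), and Mapre1 put 18 of 20 below every wild-type tumour, so a single wrong label is not excluded. For a probe set at background the values stay open: the brighter probe set lay 0.82 log2 units above the filter threshold in wild type (SD 0.26) and 0.63 in E2F1 null tumours (SD 0.42), the other 0.67 (SD 0.44) and 0.06 (SD 0.45), and this threshold is the 40th percentile of all values, not a measured background. Transcription of a part of E2f1 that the allele keeps, or binding of other transcripts, could leave this signal, and neither was tested.

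Chance as the source of the gene counts was examined with 100 splits of the label numbers, the real one included. Few splits reached the real count in the comparisons listed next, which makes chance unlikely there but does not exclude it. Against wild type, 2 of 100 splits did for E2F1 null (4 genes, highest other split 7). For E2F2 null 1 did (2 genes, highest other 1). Between E2F1 null and E2F2 null 1 did (14 genes, highest other 7). Between E2F1 null and E2F3 heterozygous 3 did (7 genes, highest other 12). Between E2F2 null and E2F3 heterozygous 1 did (3 genes, highest other 2). For the 4 genotypes 1 did (13 genes, highest other 11). Another split thus gave more genes than the real one for E2F1 null against wild type and against E2F3 heterozygous. For E2F3 heterozygous against wild type the count of 0 (58 genes at an unadjusted p under 0.05 by limma) was reached in 100 of 100 splits by construction, and the highest other count was 0, so this test is void and says nothing about chance. These statements hold for the counts past the adjusted threshold. By the number of genes at an unadjusted p under 0.05, 94 of 100 splits reached the real value for E2F1 null, 22 for E2F2 null and 100 for E2F3 heterozygous against wild type, 11 for E2F1 null against E2F2 null, 59 for E2F1 null against E2F3 heterozygous, 9 for E2F2 null against E2F3 heterozygous and 54 for the 4 genotypes, so chance cannot be excluded for any of these numbers.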
